A study of Vibrio natriegens with 18 samples.

How the data were processed

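The samples were total RNA of Vibrio natriegens grown at 20 °C with 0, 300 or 540 mM NaCl and taken at time points T1, T2 and T3, with libraries A and B for each combination, 18 libraries in all. Per the labels, ribosomal RNA was removed and directional libraries were sequenced. Of the software used by the submitters only FastQC is named, and the aligner, the counting tool and the genome build are not given in the sources used here.

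The deposited values are in TPM in 1 table per library. The 18 tables list the same genes on 41 contigs with their coding length, and each sums to 1000000 TPM. Gene names were taken from a gene table of another assembly of the species by protein accession, which matched 4261 genes, 1420 of them with a symbol. Genes sharing a symbol are named by their protein accession. In every library TPM times length was a whole multiple of 1 step for all genes, within a tolerance of 0.001, so that the reads per gene and the read total of each library were recovered. These totals lay between 39958 and 615190 with a median of 269363. They are low for such libraries, and the sources used here do not state whether the tables hold all reads, so that totals, floors and counts of 0 refer to the reads behind the tables. The highest level that a count of 0 allows was taken as 3 reads per library. For some genes with a group at 0 reads the fold change is given as a lower bound against the higher floor of that group. Fitted log2 fold changes that involve a group at or near 0 reads are also printed, and their size depends on the pseudocount. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

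The tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. They assumed read counts, and a count-based quasi-likelihood test had been planned. The deposited unit, TPM, was kept by choice, although the recovered reads would have allowed the planned test. Instead limma 3.58.1 in R 4.3.3 was used on log2(TPM + 1), with empirical Bayes moderation and a mean-variance trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. For salinity over all time points, TPM was averaged over the 3 time points of each salinity and letter and the 6 resulting culture profiles were compared, 2 per salinity, on 3078 genes. The log was taken after averaging, so the time point with the highest TPM of a gene weighs most in these fold changes. The labels do not show whether the libraries with one letter at T1 to T3 come from one vessel, and treating them as one culture is an assumption. For salinity at each time point, for time averaged over the salinities and for the difference of the 540 mM change between T3 and T1, the 18 libraries were fitted with 1 mean for each of the 9 groups. A gene was tested when it had at least 10 reads, scaled from the median depth, in at least 2 libraries and at least 15 reads in total. Comparisons with T3 used the 1176 genes whose mean TPM corresponds to at least 5 reads in the shallowest library. Both filters and the average per culture were chosen after the depth had been seen and before any test was run. In the text, ± after TPM is the SD, ± after a log2 fold change is the limma standard error, and groups in a comparison have n = 2 cultures, 2 libraries or, for time, 6 libraries.

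The letters A and B are the only replicate labels. Fits with the letter or the culture as a block are given among the alternatives. The labels do not say how the 2 libraries of a group are separate beyond the letter, so that p-values measure the spread between these samples. The fits of the 18 libraries use 1 spread per gene for all 9 groups. A test at 1 time point thus does not measure the spread at that time point alone. For proX the standard error was 0.62 at T1, T2 and T3 alike. Because replicates correlated less at T3, standard errors may be too small there and too large at T1 and T2.

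Lists of genes of bacterial pathways were matched by symbol or product text and tested with camera of limma, with a preset correlation between genes of 0.01, and again with an estimated correlation. Adjusted p of lists are Benjamini-Hochberg values over the lists of a comparison, 30 lists or, with T3, 24. Beside each count of called members stands the count when adjusted over the list alone. Genes were named by rule in the text. For 540 against 0 mM and for T3 against T1 these were the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a change of at least 2-fold, the same sign at each time point or in each salinity, a mean of at least 20 TPM in a compared condition and an annotated symbol or product. For other comparisons these were the 5 largest in each direction, without the condition on sign for the difference of differences. Any member of the ectoine, glycine betaine and choline, osmolyte uptake, potassium, sodium, mechanosensitive channel and aquaporin, and porin lists could also be named for salinity, and 2 to 4 members of another list, those with the smallest adjusted p in the direction described. Not every gene that meets the rule is named, and the gene results followed through the alternatives are those named in the text with others that meet the rule, 226 in all.

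TPM values add to a fixed total, so each comparison was also run after scaling by median of ratios over 1908 genes (factors 0.804 to 1.61). Other alternatives were other filters and pseudocounts (0.1 and 5), a least change of 2-fold, the block, unsummed libraries, voom with the culture as a random block, libraries thinned to the shallowest, each time point, library or culture left out, and fits on only the libraries compared. After the data had been seen, array weights by time point, the mean of log2 values, summed reads, left-out cultures, the T3 depth filter left out (also with thinning, for the nitrogen list), and list counts under scaling or without T3 or 0 mM T3 B were added. The tests were tried on simulated libraries of these depths with 200 changed genes. The simulation used a dispersion of 0.02 for every gene, the same mean profile at each time point and no effect of culture. Its changes were dealt so that the total stayed nearly the same. The rates below hold for that setting only, which is simpler than the real libraries. Of genes changed 4-fold, 94.7% were called in the salinity comparison over time, 52.1% at T1, 95.9% at T3 and 100% for T3 against T1, and of unchanged genes 0.153%, 0%, 2.78% and 1.52%. Of genes changed 2-fold, 54.7%, 12.6%, 58.6% and 95.9% were called in these comparisons, so that 2-fold changes at T1 were often not detectable. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.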

Results

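RNA was sequenced from Vibrio natriegens, a fast-growing marine bacterium, grown at 20 °C in a modified minimal medium in parallel bioreactors. The cultures held 0, 300 or 540 mM NaCl and were sampled at 3 time points, T1, T2 and T3, with 2 libraries per combination, A and B. This gave 18 libraries in 9 groups of 2. The series also describes other temperatures, metabolites and proteins, which are not analysed here. The times behind T1 to T3 are not given in the sources used here. It is thus not known whether cultures of different salinity were at a like stage of growth at one time point. Values are in TPM, the share of transcripts corrected for gene length, and 4473 annotated genes had at least 1 read. The read totals recovered from the files were low, between 39958 and 615190 per library with a median of 269363. They ran from 184954 to 547430 at T1, from 167263 to 615190 at T2 and from 39958 to 159015 at T3.

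The T3 libraries lay apart from all others, as the plot of principal components shows. Across 1176 genes the correlation of log2 values between replicates was 0.971 to 0.986 at T1 and T2. At T3 it was 0.793 at 0 mM, 0.883 at 300 mM and 0.955 at 540 mM NaCl. In the 0 mM T3 library B, 24 genes lay more than 4 times under the lowest of the other T3 libraries, against 1 to 11 genes in each of those. Principal component 1 held 75.2% of the variance and principal component 2 held 9.33%. These correlations are across genes, which are not independent replicates.

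**Figure D1:**
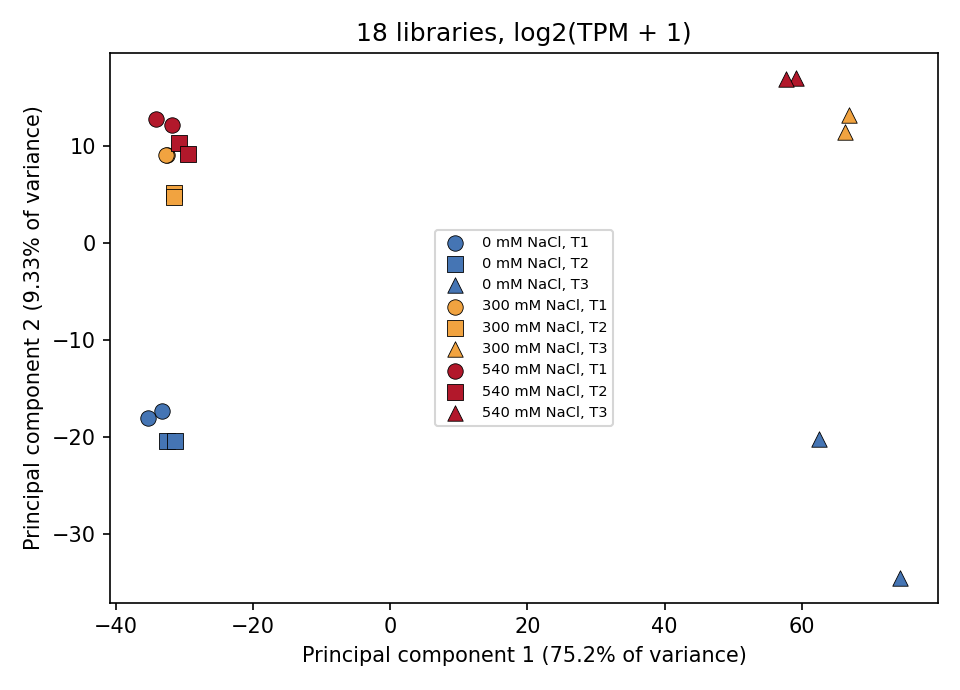
Each point is 1 of the 18 libraries, placed by the first principal components of log2(TPM + 1), with the share of variance on each axis. The T3 libraries sit between 57.6 and 74.3 on component 1 and all T1 and T2 libraries between -35.3 and -29.5, while component 2 sets the 0 mM libraries below those with salt.

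The first comparison asked which transcripts differed between cultures with 540 mM NaCl and cultures without added NaCl, averaged over the 3 time points. Among the largest rises were genes for making and importing compatible solutes, the small organic molecules that balance external salt. Transcripts of ectB, whose product opens the pathway to the compatible solute ectoine, rose from 14.5 ± 19.3 to 1945 ± 17.5 TPM (SD, n = 2 cultures each; log2 fold change 8.04 ± 1.11 SE, adjusted p = 0.00711). The ectoine synthase WP_020336355.1 rose from 22.3 ± 17.5 to 2797 ± 42.6 TPM (log2 fold change 7.15 ± 0.50, adjusted p = 9.52e-04). Transcripts of proX, the binding protein of a glycine betaine and proline importer, rose from 18.7 ± 17.9 to 2334 ± 264 TPM (log2 fold change 7.28 ± 0.64, adjusted p = 0.00185). The porin WP_014231315.1 rose from 1258 ± 372 to 10040 ± 95 TPM and the porin WP_020333911.1 fell from 7787 ± 804 to 3075 ± 167 TPM.

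Of the 7 measured genes of the ectoine list, 5 rose and 1 fell, also when adjusted over the list alone. The list as a set had a camera adjusted p = 0.0513. Transcripts of ectA, which acetylates diaminobutyrate, rose by a log2 fold change of 8.28 ± 1.38 (adjusted p = 0.0132), and the aspartate kinase WP_014231961.1 beside them rose by 6.81 ± 0.50 (adjusted p = 0.00117). These genes and the synthase WP_020336355.1 lie in a row on contig 44 of an assembly whose build is not stated. There ectA lies at 62506 to 63039, ectB at 61205 to 62470, the synthase at 60803 to 61189 and the kinase at 59288 to 60712. A second ectoine synthase, WP_014235031.1, lies on contig 8 at 150467 to 150853 and rose by 7.68 ± 0.87 (adjusted p = 0.00393). That rise rested on T3, and its log2 fold change was -0.43 with T3 left out. The member that fell, WP_020335559.1, is annotated as a family member of the EctB transaminase (log2 fold change -1.21 ± 0.21, adjusted p = 0.0147).

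Osmolyte uptake rose as a set, with 5 of 8 genes higher and 0 lower (6 higher when adjusted over the list alone; camera adjusted p = 5.27e-05). The list had an adjusted p = 0.483 with an estimated correlation. Its members proV and proW, the energy subunit and permease of the proX importer, rose by 7.68 ± 0.83 (adjusted p = 0.00344) and 7.44 ± 0.27 (adjusted p = 6.30e-05). Importers of the BCCT family, which take up betaine, carnitine or choline, included WP_020335534.1, which rose from 26.6 ± 7.12 to 553 ± 37.8 TPM (log2 fold change 4.35 ± 0.22, adjusted p = 2.09e-04). Another, WP_020333247.1, had a log2 fold change of 4.38 ± 0.22 (adjusted p = 2.09e-04). Of the 7 genes for making glycine betaine from choline or importing choline, 3 rose and 0 fell (4 when adjusted over the list alone; camera adjusted p = 0.122). Among them the choline importer subunit choW rose by 4.80 ± 0.50 (adjusted p = 0.00334). Of 12 porin genes, 2 rose and 1 fell (3 and 1 when adjusted over the list alone; camera adjusted p = 0.958). Besides the pair above, the porin WP_014233529.1 rose by 2.15 ± 0.24 (adjusted p = 0.00344).

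**Figure D2:**
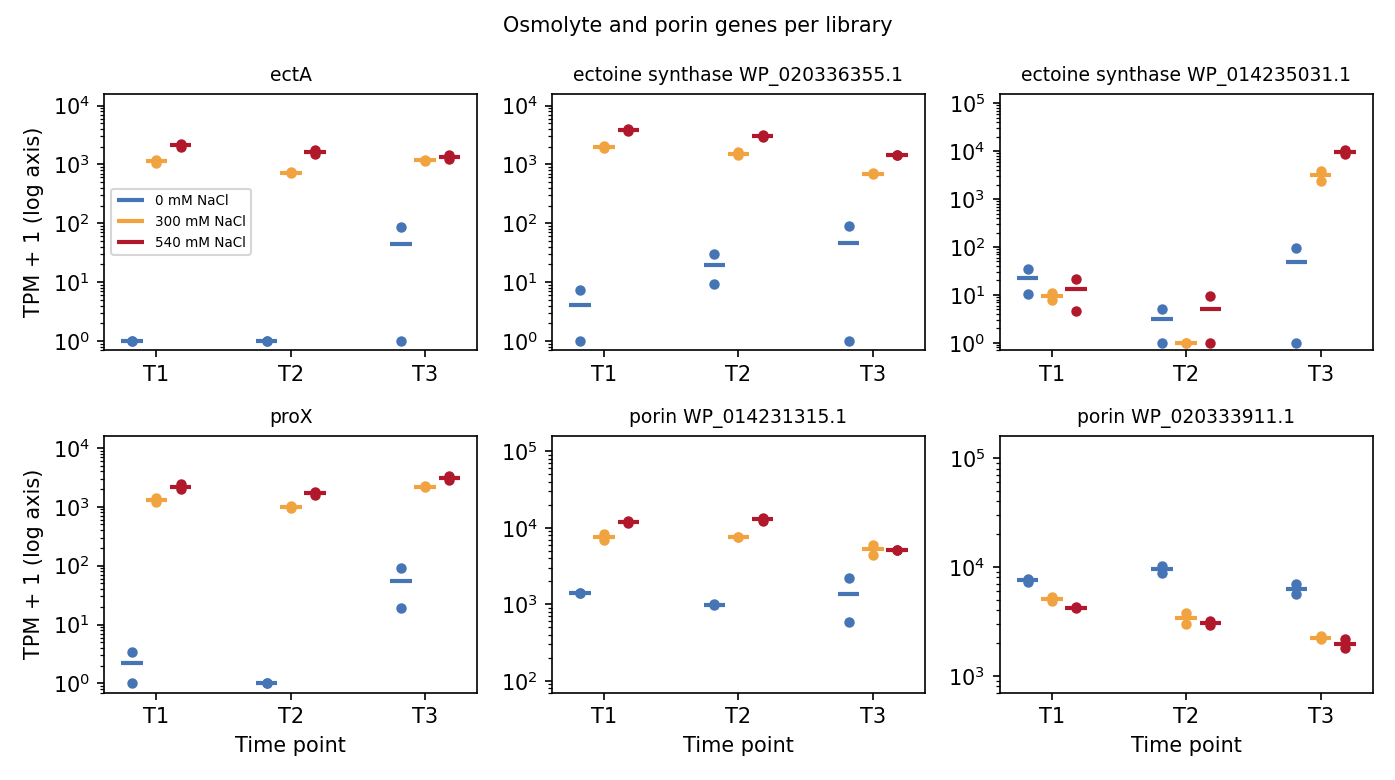
TPM + 1 on a log axis for 6 osmolyte and porin genes at the 3 time points, coloured by NaCl concentration, with points for the 2 libraries and bars for the group mean. The genes ectA and proX and the ectoine synthase WP_020336355.1 were high with salt at every time point, the synthase WP_014235031.1 was high with salt at T3, where it reached 9598 TPM at 540 mM, and the 2 porins moved in opposite directions.

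Of 18 sodium transport genes, 1 rose and 1 fell (camera adjusted p = 0.896; 1 and 1 when adjusted over the list alone). The antiporter WP_020333874.1, annotated as NhaC and so as an exchanger of sodium ions for protons, fell from 207 ± 78.5 to 18.3 TPM (log2 fold change -3.39 ± 0.35, adjusted p = 0.00335). A second NhaC gene, WP_020334217.1, rose by 2.39 ± 0.54 (adjusted p = 0.0319), a call lost without any 1 of the 6 cultures, at adjusted p of up to 0.194. No gene of the potassium transport list passed in limma (0 of 8, with 2 at an unadjusted p under 0.05), and trkA had a log2 fold change of 0.49 ± 0.27. None of 7 mechanosensitive channel and aquaporin genes passed in limma either (3 when adjusted over the list alone, 4 at an unadjusted p under 0.05), with mscS at 0.49 ± 0.13. This gene did pass with the letter as a block, with unsummed libraries, with T1 left out and with T2 left out, at adjusted p = 0.0188, 0.0197, 0.0419 and 0.0495.

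With 540 mM NaCl the glutamine synthetase WP_020332829.1 fell from 461 ± 59.7 to 3.74 TPM (log2 fold change -6.60 ± 0.58, adjusted p = 0.00188), and the aminotransferase WP_020332830.1 fell from 728 ± 71.6 to 4.94 ± 0.939 TPM (-6.94 ± 0.41, adjusted p = 4.32e-04). The solute-binding protein WP_014231257.1 fell from 1535 ± 147 to 15 ± 1.31 TPM (-6.59 ± 0.23, adjusted p = 6.30e-05), and potG, the energy subunit of a putrescine importer, fell by 5.76 on the log2 scale (SE 0.57, adjusted p = 0.00294). Of 16 nitrogen assimilation genes 4 fell and 2 rose (5 and 2 when adjusted over the list alone), and the list was lower as a set (camera adjusted p = 0.0197, and adjusted p = 0.483 with an estimated correlation). The urease gene ureC fell by 5.27 (SE 0.57, adjusted p = 0.00344), while nifH, for the nitrogenase iron protein, rose by 4.39 ± 0.52 (adjusted p = 0.00416) and the nitrate reductase gene napA by 1.54 ± 0.40 (adjusted p = 0.0461). At T3 nifH had 0 reads at 0 mM and 86.1 TPM at 540 mM. This was at least 1.40-fold above the floor of 61.5 TPM for 3 reads, so the size of its rise is not exact. The call of napA was lost without any 1 of the 6 cultures and that of nifH without 540 mM B, at adjusted p of up to 0.208. With T3 left out ureC stood at 0.28, nifH stood at 0.37, and 0 of the 16 genes rose or fell. Without salt the averaged TPM of WP_020332829.1 and WP_014231257.1 also came almost wholly from T3, whose values are given below. The log2 fall of WP_020332829.1 was larger at T3 than at T1, with a difference of -7.54 ± 1.99 (limma adjusted p = 0.0202). Its level at T3 with 540 mM lay under the floor of 3 reads, so the size of this difference is not exact. Its level without salt was low at T1, where a fall could hardly show. The difference thus does not show that the response to salt itself changed.

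With 540 mM NaCl, 21 of 60 flagellar and chemotaxis genes rose and 0 fell (34 when adjusted over the list alone; camera adjusted p = 1.54e-06, and adjusted p = 0.483 with an estimated correlation). Examples are fliS, a chaperone for flagellin export, at 2.21 ± 0.24 (adjusted p = 0.00344), the filament cap gene fliD at 1.86 ± 0.20 and the flagellin WP_020333613.1, which rose from 473 ± 124 to 1311 ± 26.1 TPM. Of 22 genes for aerobic respiration and ATP synthase, 7 rose and 0 fell (13 when adjusted over the list alone; camera adjusted p = 0.0102, and adjusted p = 0.483 with an estimated correlation). They include the terminal oxidase genes cyoA at 1.34 ± 0.18 and ccoN at 1.02 ± 0.13. Of 15 tricarboxylic acid cycle genes 6 rose, against 4 risen and 1 fallen under median-of-ratios scaling (6 when adjusted over the list alone; camera adjusted p = 0.273). For histidine and tryptophan synthesis 7 of 14 genes rose and 1 fell, against 0 and 1 under median-of-ratios scaling and 0 and 0 with T3 left out (8 and 1 when adjusted over the list alone; camera adjusted p = 0.0949).

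In all, 530 of 3078 genes passed, 345 higher and 185 lower, and 365 of them changed at least 2-fold. Under median-of-ratios scaling, which moved the median log2 fold change of all genes by -0.31, 523 genes passed with 173 higher and 350 lower, so the share of higher genes depends on the scaling. With either 540 mM culture left out, 99 (without A) and 97 (without B) genes passed, and ectA, ectB, ccoN, cyoA, WP_020335559.1 and the flagellin WP_020333613.1 lost their calls in either fit, at adjusted p of up to 0.111.

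At 300 mM NaCl these solute genes were already far above their level without salt. Transcripts of ectB rose from 14.5 ± 19.3 to 984 ± 61.9 TPM (n = 2 cultures each; log2 fold change 7.05 ± 1.11, adjusted p = 0.0164). Those of proW rose from 3.0 ± 1.32 to 513 ± 35.4 TPM (7.04 ± 0.27, adjusted p = 1.26e-04). The synthase WP_020336355.1 rose to 1397 ± 81.5 TPM (6.15 ± 0.50, adjusted p = 0.00226) and proX to 1503 ± 114 TPM (6.64 ± 0.64, adjusted p = 0.0041). The porin WP_014231315.1 rose by 2.46 ± 0.20 and the porin WP_020333911.1 fell by 1.13 (SE 0.13, adjusted p = 0.00559).

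Of the 7 ectoine genes 5 rose and 0 fell (5 and 1 when adjusted over the list alone; camera adjusted p = 0.00486, and adjusted p = 0.481 with an estimated correlation). Of these 5, the synthase WP_014235031.1 stood at -1.21 with T3 left out and lost its call without 300 mM A or B, at adjusted p of up to 0.0875. Of the 8 osmolyte uptake genes 5 rose and 0 fell (5 when adjusted over the list alone; camera adjusted p = 2.87e-04, and adjusted p = 0.663 with an estimated correlation), with the BCCT importer WP_020335534.1 at 3.84 ± 0.22. Flagellar genes were higher as a set, with 17 of 60 risen and 0 fallen (27 when adjusted over the list alone; camera adjusted p = 4.86e-08, and adjusted p = 0.395 with an estimated correlation). Respiration genes were too, with 6 of 22 risen and 0 fallen (12 when adjusted over the list alone; camera adjusted p = 0.00171, and adjusted p = 0.395 with an estimated correlation). The fermentation list was lower, a call lost with the letter as a block (camera adjusted p = 0.0472, and adjusted p = 0.663 with an estimated correlation). In it 1 of 5 genes fell (2 when adjusted over the list alone). It was pflB, whose enzyme splits pyruvate to formate (log2 fold change -1.01 ± 0.22, adjusted p = 0.0395). The falls again included the aminotransferase WP_020332830.1 at -6.51 ± 0.41 (adjusted p = 0.00108), the solute-binding protein WP_014231257.1 at -5.67 ± 0.23 and potG at -5.46 ± 0.57.

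For 300 mM, 328 of 3078 genes passed, 191 higher and 137 lower. Under median-of-ratios scaling, with a shift of the median of -0.26, 346 passed with 106 higher and 240 lower. The count was 45 without culture 300 mM A, 95 without 300 mM B, 108 without 540 mM A and 113 without 540 mM B. In each of these 4 fits ectA and ectB lost their calls, at adjusted p of up to 0.120, and pflB lost its call without any 1 of the 6 cultures, at adjusted p of up to 0.139.

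Between 300 and 540 mM NaCl 5 genes passed, all lower at 540 mM in this fit, and none of the 5 passed with unsummed libraries or voom. The urea importer subunit urtA fell from 870 ± 98.7 to 223 ± 7.14 TPM (n = 2 cultures each; log2 fold change -1.96 ± 0.16, adjusted p = 0.01), after 3197 ± 502 TPM without salt. The remaining 4 were chosen after their values were seen, since they fall outside the rule for named genes. The first was the histidinol-phosphate transaminase WP_024373008.1 (516 ± 64.4 to 82.6 ± 12.1 TPM, log2 fold change -2.63 ± 0.19, adjusted p = 0.01). Next was the ABC importer binding protein WP_014233674.1 (472 ± 33.4 to 115 ± 15.7 TPM, -2.04 ± 0.15, adjusted p = 0.01). The other 2 were the dipeptide epimerase WP_020335356.1 (-1.40 ± 0.15, adjusted p = 0.0349) and WP_020335355.1, a protein with a domain of unknown function (-1.38 ± 0.14, adjusted p = 0.0349). The histidine and tryptophan list was higher as a set, with a median log2 fold change of 0.38 (camera adjusted p = 0.0224, and adjusted p = 0.579 with an estimated correlation). Of its 14 genes 0 rose and 1 fell, the transaminase WP_024373008.1, and 3 rose and 1 fell when adjusted over the list alone.

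Of 3078 genes 5 passed, 0 higher and 5 lower, and 267 had an unadjusted p under 0.05. The ectoine gene ectB had 984 TPM at 300 mM and 1945 TPM at 540 mM and did not pass. The 5 calls rest on T3, since 0 genes passed in limma with T3 left out (250 at an unadjusted p under 0.05). Unsummed libraries gave 29 genes, 25 higher and 4 lower, and voom 29, 20 higher and 9 lower, and in both WP_024373008.1, WP_020335355.1 and WP_020335356.1 turned positive. Without 300 mM A, 300 mM B, 540 mM A or 540 mM B 0 genes passed in limma (239, 240, 144 and 187 at an unadjusted p under 0.05), with an adjusted p of 0.105 to 0.333 for the 5 genes. Without 0 mM A or B 12 genes passed.

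At T1, 540 mM against 0 mM NaCl showed several solute genes nearly silent without salt. No read of ectA was found in either 0 mM library, and at 540 mM it stood at 2095 ± 137 TPM (SD, n = 2 libraries each), at least 111-fold above the floor of 3 reads per library (adjusted p = 5.52e-04). Likewise proV had 0 reads without salt and 516 ± 5.03 TPM at 540 mM, at least 61.1-fold above that floor. Transcripts of proX rose from 1.22 to 2197 ± 295 TPM (log2 fold change 10.20 ± 0.62, adjusted p = 1.62e-06). Those of the BCCT importer WP_020335534.1 rose from 13.1 ± 3.53 to 689 ± 15.4 TPM (5.63 ± 0.27, adjusted p = 1.43e-07). In the other direction, speA and speB, which make putrescine from arginine, fell from 143 ± 2.0 to 2.48 TPM (-5.38 ± 0.65, adjusted p = 5.52e-04) and from 241 ± 52.2 to 5.11 TPM (-5.30 ± 0.55, adjusted p = 2.14e-04).

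Osmolyte uptake was higher as a set with either correlation setting, with 5 of 8 genes risen and 0 fallen (6 when adjusted over the list alone; camera adjusted p = 1.24e-12, and adjusted p = 0.0424 with an estimated correlation). Glycine betaine and choline genes followed with 5 of 7 risen and 0 fallen (5 when adjusted over the list alone; camera adjusted p = 1.19e-06, and adjusted p = 0.105 with an estimated correlation). Among them betA, the choline dehydrogenase gene, rose by 4.45 ± 0.61 (adjusted p = 0.00137). Of 7 ectoine genes 4 rose and 1 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.00733, and adjusted p = 0.105 with an estimated correlation). The porin WP_014231315.1 rose from 1403 to 11960 ± 558 TPM (3.09 ± 0.42, adjusted p = 0.00127).

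The envelope stress list was lower as a set (camera adjusted p = 0.00257, and adjusted p = 0.113 with an estimated correlation), with 2 of 24 genes fallen and 0 risen (3 when adjusted over the list alone). These were rpoE, the sigma factor of the envelope stress response, from 1158 ± 95.1 to 308 ± 12.2 TPM (-1.90 ± 0.17, adjusted p = 7.82e-05), and its negative regulator WP_014233000.1 at -1.61 ± 0.20. Ribosomal protein genes were also lower (camera adjusted p = 0.00113, and adjusted p = 0.383 with an estimated correlation), with 2 of 59 fallen and 0 risen (2 when adjusted over the list alone and 5 under median-of-ratios scaling). These were rpsT (-0.99 ± 0.21) and WP_014233536.1, an enzyme that modifies ribosomal protein S6. Flagellar genes were higher with 4 risen and 0 fallen (4 when adjusted over the list alone; camera adjusted p = 0.00113, and adjusted p = 0.251 with an estimated correlation). Heat shock genes were called with 1 of 17 risen, clpA (2 when adjusted over the list alone and 0 under median-of-ratios scaling; camera adjusted p = 0.00242, and adjusted p = 0.338 with an estimated correlation). Branched-chain amino acid synthesis was called with 1 of 12 risen, ilvG (4 when adjusted over the list alone; camera adjusted p = 0.0349, and adjusted p = 0.383 with an estimated correlation).

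In total 115 of 3078 genes passed at T1, 77 higher and 38 lower. Under median-of-ratios scaling, with a shift of -0.22, 118 passed with 53 higher and 65 lower. Without library 0 mM T1 A 47 genes passed, without 540 mM T1 A 45, without 0 mM T3 A 199 and without 0 mM T3 B 200. The calls of clpA, ilvG and rpsT were lost without 0 mM T1 A, 540 mM T1 A or 0 mM T1 B, and that of WP_014233536.1 without any of the 4 libraries compared, at adjusted p of up to 0.207.

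At T2 the solute genes were again higher with 540 mM NaCl. Transcripts of proX went from 0 reads without salt to 1689 ± 124 TPM at 540 mM (n = 2 libraries each), at least 149-fold above the floor of 3 reads per library (adjusted p = 9.23e-07). Those of ectA went from 0 reads to 1654 ± 191 TPM, at least 77.0-fold above it (adjusted p = 5.27e-04). The porin WP_014231315.1 rose from 990 to 13010 ± 769 TPM (log2 fold change 3.71 ± 0.42, adjusted p = 2.61e-04) while the porin WP_020333911.1 fell from 9502 ± 1053 to 3044 ± 168 TPM (-1.64 ± 0.16, adjusted p = 9.15e-05). The tricarboxylic acid cycle genes mdh and sdhA, for malate and succinate dehydrogenase, rose from 114 ± 11.3 to 515 ± 105 TPM (2.15 ± 0.33, adjusted p = 0.0023) and from 196 to 519 ± 21.3 TPM (1.40 ± 0.16, adjusted p = 2.83e-04).

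That list was called with either correlation setting, with 6 of 15 genes risen and 0 fallen (7 when adjusted over the list alone; camera adjusted p = 8.98e-05, and adjusted p = 0.0388 with an estimated correlation). So was osmolyte uptake with 5 of 8 risen and 0 fallen (5 when adjusted over the list alone; camera adjusted p = 1.90e-10, and adjusted p = 0.0388 with an estimated correlation). Flagellar genes had 13 risen and 0 fallen (15 when adjusted over the list alone; camera adjusted p = 7.50e-07, and adjusted p = 0.0517 with an estimated correlation). Glycine betaine and choline genes had 5 risen and 0 fallen (6 when adjusted over the list alone; camera adjusted p = 5.61e-06, and adjusted p = 0.0517 with an estimated correlation). Ectoine genes had 4 risen and 0 fallen (4 and 1 when adjusted over the list alone; camera adjusted p = 0.00565, and adjusted p = 0.0517 with an estimated correlation). The envelope stress list had 0 risen and 2 fallen (2 when adjusted over the list alone; camera adjusted p = 5.42e-04, and adjusted p = 0.0517 with an estimated correlation), rpoE at -1.70 ± 0.17 and its regulator WP_014233000.1. Respiration genes were higher, 3 risen and 0 fallen (5 when adjusted over the list alone; camera adjusted p = 0.00229, and adjusted p = 0.350 with an estimated correlation), with the oxidase gene ccoO at 1.51 ± 0.24. Ribosomal protein genes were lower as a set with 1 of 59 fallen (1 when adjusted over the list alone and 3 under median-of-ratios scaling; camera adjusted p = 0.00465, and adjusted p = 0.497 with an estimated correlation).

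At T2 143 of 3078 genes passed, 111 higher and 32 lower, and under median-of-ratios scaling, with a shift of -0.16, 150 passed with 89 higher and 61 lower. Without 540 mM T2 A 58 genes passed, without 540 mM T2 B 66, and without 0 mM T3 A or B 273. The calls of betA, at 2.96 ± 0.61, and of the synthase WP_020336355.1, at 7.51 ± 1.51, were lost without 0 mM T2 B or either 540 mM T2 library, at adjusted p of up to 0.144.

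At T3 the second ectoine synthase, WP_014235031.1, had the largest fitted rise of the genes tested, from 46.7 ± 66.1 to 9598 ± 1415 TPM (n = 2 libraries each; log2 fold change 9.94 ± 1.73, adjusted p = 0.00101). Its level without salt lies under the floor of 3 reads. That floor was 54.2 TPM on 1000 bp in 0 mM T3 A and is higher for this shorter gene. The size of this rise and its rank thus depend on the pseudocount. Transcripts of ectA (7.17 ± 1.34, adjusted p = 0.00149), proV (7.45 ± 0.92, adjusted p = 1.31e-04) and proX (6.21 ± 0.62, adjusted p = 2.54e-05) were again higher with salt. Against these, the glutamine synthetase WP_020332829.1 fell from 1353 ± 167 to 1.72 ± 2.44 TPM (-9.32 ± 1.41, adjusted p = 4.42e-04). The solute-binding protein WP_014231257.1 fell from 4540 ± 455 to 35.3 ± 2.72 TPM (-6.97 ± 0.44, adjusted p = 1.40e-06). The ribosome-binding factor RaiA, WP_020335943.1, fell from 12350 ± 4329 to 2649 ± 263 TPM (-2.18 ± 0.33, adjusted p = 4.52e-04).

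All 5 osmolyte uptake genes measured at this depth rose (5 when adjusted over the list alone; camera adjusted p = 0.00177, and adjusted p = 0.292 with an estimated correlation). At the same time point 5 of 7 ectoine genes rose and 0 fell (5 and 1 when adjusted over the list alone; camera adjusted p = 0.220). Of 56 ribosomal protein genes 27 rose and 0 fell (27 when adjusted over the list alone), against 5 risen under median-of-ratios scaling and 39 without 0 mM T3 B (camera adjusted p = 0.0292, and adjusted p = 0.572 with an estimated correlation). Flagellar genes had 10 of 13 risen and 0 fallen (11 when adjusted over the list alone and 5 under median-of-ratios scaling; camera adjusted p = 0.0274, and adjusted p = 0.440 with an estimated correlation). Glycolysis was lower with 3 of 8 fallen and 1 risen (4 and 1 when adjusted over the list alone; camera adjusted p = 0.0274, and adjusted p = 0.440 with an estimated correlation). Its gene pfkA fell from 1314 to 579 TPM (-1.18 ± 0.19, adjusted p = 7.01e-04). The nitrogen list was lower with 2 of 6 fallen and 0 risen (2 when adjusted over the list alone; camera adjusted p = 0.0338, and adjusted p = 0.292 with an estimated correlation). Arginine synthesis was lower with 3 of 10 fallen and 1 risen (3 and 1 when adjusted over the list alone), against 2 fallen and 3 risen without 0 mM T3 B (camera adjusted p = 0.0338, and adjusted p = 0.442 with an estimated correlation). Its gene argH fell by 2.44 (SE 0.37, adjusted p = 4.75e-04). Of 13 histidine and tryptophan genes 9 rose and 1 fell (9 and 1 when adjusted over the list alone; camera adjusted p = 0.0848), with hisA rising from 232 to 912 ± 65.0 TPM (1.97 ± 0.24, adjusted p = 1.18e-04).

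Of the 1176 genes deep enough to test at T3, 532 passed, 397 higher and 135 lower. Under median-of-ratios scaling, with a shift of -0.50, 408 passed with 175 higher and 233 lower, so the balance of directions turns with the scaling. A fit on only the 4 libraries compared gave 62 genes, 33 higher and 29 lower, and 13 of 22 T3 gene results followed lost their call, while array weights by time point gave 178 genes and ended 2 of these calls.

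The next comparison followed the cultures from T1 to T2, averaged over the 3 salinities. The ribosomal protein L31 gene of type B, WP_020335158.1, a paralog that lacks the zinc-binding cysteines of the main form in many bacteria, rose from 49.0 ± 50.6 to 5824 ± 1102 TPM (SD, n = 6 libraries each; log2 fold change 7.97 ± 0.87, adjusted p = 3.33e-04). The L36 gene ykgO rose from 45.7 ± 52.6 to 3778 ± 717 TPM (7.52 ± 1.61, adjusted p = 0.0204). The main L31 gene rpmE fell from 4457 ± 1218 to 1394 ± 361 TPM (-1.68 ± 0.29, adjusted p = 0.00618). Beside these, znuA, the binding protein of the zinc importer, chosen after its values were seen, rose from 82.6 to 666 ± 121 TPM (2.99 ± 0.57, adjusted p = 0.0122). The binding protein WP_020334791.1 and the permease WP_020334792.1 of an ABC importer rose by 5.88 ± 0.93 (adjusted p = 0.00352) and 5.74 ± 0.80 (adjusted p = 0.00144).

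**Figure D3:**
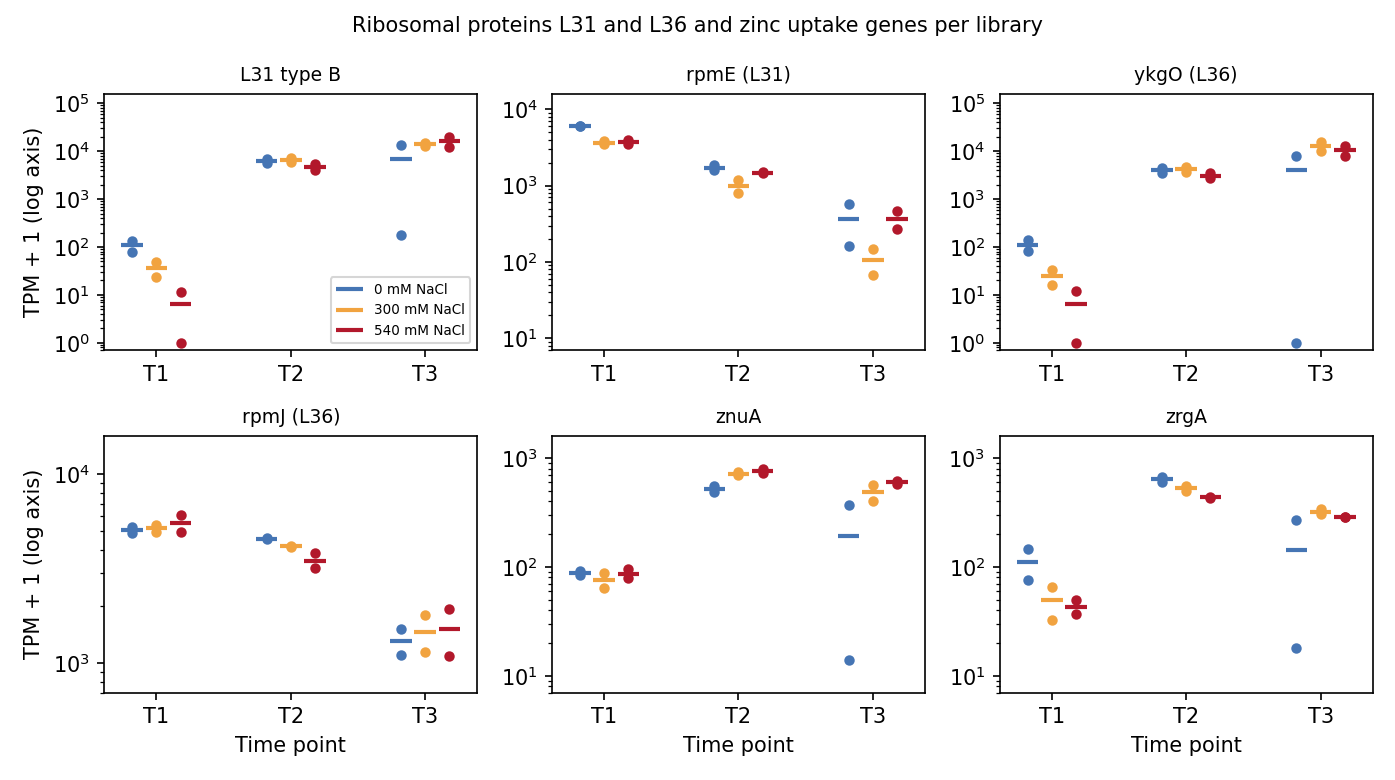
TPM + 1 on a log axis for ribosomal protein genes L31 and L36 and for zinc uptake genes at the 3 time points, coloured by NaCl concentration, with points for the 2 libraries and bars for the group mean. Type B L31 and ykgO rose from T1 to T2 at each salinity while rpmE fell, and in library B at 0 mM T3 type B L31 had 181 TPM, ykgO 0 TPM and znuA 13.1 TPM.

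Of 15 tricarboxylic acid cycle genes 5 fell at T2 and 0 rose (10 when adjusted over the list alone; camera adjusted p = 1.00e-05, and adjusted p = 0.0137 with an estimated correlation). Among them sucA fell by 0.84 (SE 0.10, adjusted p = 6.00e-04). Of 14 histidine and tryptophan genes 6 fell and 0 rose (10 and 1 when adjusted over the list alone; camera adjusted p = 8.80e-06, and adjusted p = 0.0137 with an estimated correlation), with hisB at -0.82 ± 0.15. These were the lists called with either correlation setting. Branched-chain amino acid synthesis had 6 of 12 fallen and 0 risen (8 when adjusted over the list alone; camera adjusted p = 4.30e-07, and adjusted p = 0.0582 with an estimated correlation), with ilvD at -0.79 ± 0.10. Proline and glutamate metabolism had 3 of 14 fallen and 1 risen (5 and 1 when adjusted over the list alone; camera adjusted p = 0.00291, and adjusted p = 0.0582 with an estimated correlation). The glutamate synthase gene WP_020335903.1 fell from 1217 to 605 TPM (-1.01 ± 0.09, adjusted p = 7.79e-05). Respiration had 8 of 22 fallen, 3 under median-of-ratios scaling (8 when adjusted over the list alone; camera adjusted p = 7.93e-04, and adjusted p = 0.367 with an estimated correlation). Sodium transport had 5 of 18 fallen (5 when adjusted over the list alone; camera adjusted p = 0.0204, and adjusted p = 0.0886 with an estimated correlation). Among the remaining called lists, sulfur assimilation had 3 fallen, heat shock, glycolysis and the pentose phosphate pathway 2 each and arginine synthesis 1, at camera adjusted p of 0.00225, 0.00961, 0.0234, 0.0304 and 0.0271. When adjusted over the list alone 4, 4, 3, 2 and 2 fell, and under median-of-ratios scaling 1, 0, 1, 1 and 0 fell. Their adjusted p lay between 0.381 and 0.413 with an estimated correlation. Ribosomal protein genes went both ways, 5 risen and 5 fallen (7 and 8 when adjusted over the list alone; camera adjusted p = 0.829), with rpsT rising from 11540 ± 3937 to 30380 ± 9486 TPM.

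From T1 to T2, 147 of 3078 genes passed, 62 higher and 85 lower, and 35 of them changed at least 2-fold. Under median-of-ratios scaling 126 passed with 72 higher and 54 lower, so the balance of directions turns with the scaling. Between 70 and 78 genes passed without any 1 of 0 mM T1 A, 300 mM T1 A, 300 mM T2 A, 540 mM T1 A, 540 mM T2 A, 300 mM T2 B or 540 mM T2 B, while 245 passed without 0 mM T3 A or B. The call of ykgO was lost in each of the first 7 fits and without 0 mM T2 B (adjusted p of up to 0.0722).

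The ammonium transporter WP_014232922.1 rose from 26.2 ± 7.62 TPM at T1 to 23960 ± 1378 TPM at T3 (SD, n = 6 libraries each; log2 fold change 9.84 ± 0.16, adjusted p = 3.22e-13). The nitrogen regulator of the P-II family WP_005386570.1, which senses the nitrogen state of the cell, rose from 18.8 ± 11.8 to 30300 ± 2414 TPM (11.13 ± 0.59, adjusted p = 2.59e-09). The urea importer gene urtA rose to 4287 ± 4252 TPM (10.67 ± 0.41, adjusted p = 2.12e-10), and its T3 level was 9587 TPM at 0 mM, 2608 TPM at 300 mM and 667 TPM at 540 mM NaCl. At 540 mM urtA had 0 reads at T1, so its rise there was at least 70.3-fold above the floor of 3 reads per library. Transcripts of eutC, for a subunit of ethanolamine ammonia-lyase, went from 0 reads at T1 to at least 357-, 251- and 88.7-fold above the floor of 3 reads per library at 0, 300 and 540 mM (adjusted p = 9.10e-11). The xanthine dehydrogenase gene xdhA reached 2183 ± 162 TPM (10.94 ± 0.39, adjusted p = 1.07e-10). At 300 and 540 mM xdhA had 0 reads at T1 and at T3 stood at least 539- and 236-fold above that floor. In the other direction, rplB for ribosomal protein L2 fell from 9417 ± 564 to 781 ± 214 TPM (-3.63 ± 0.14, adjusted p = 1.93e-10).

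**Figure D4:**
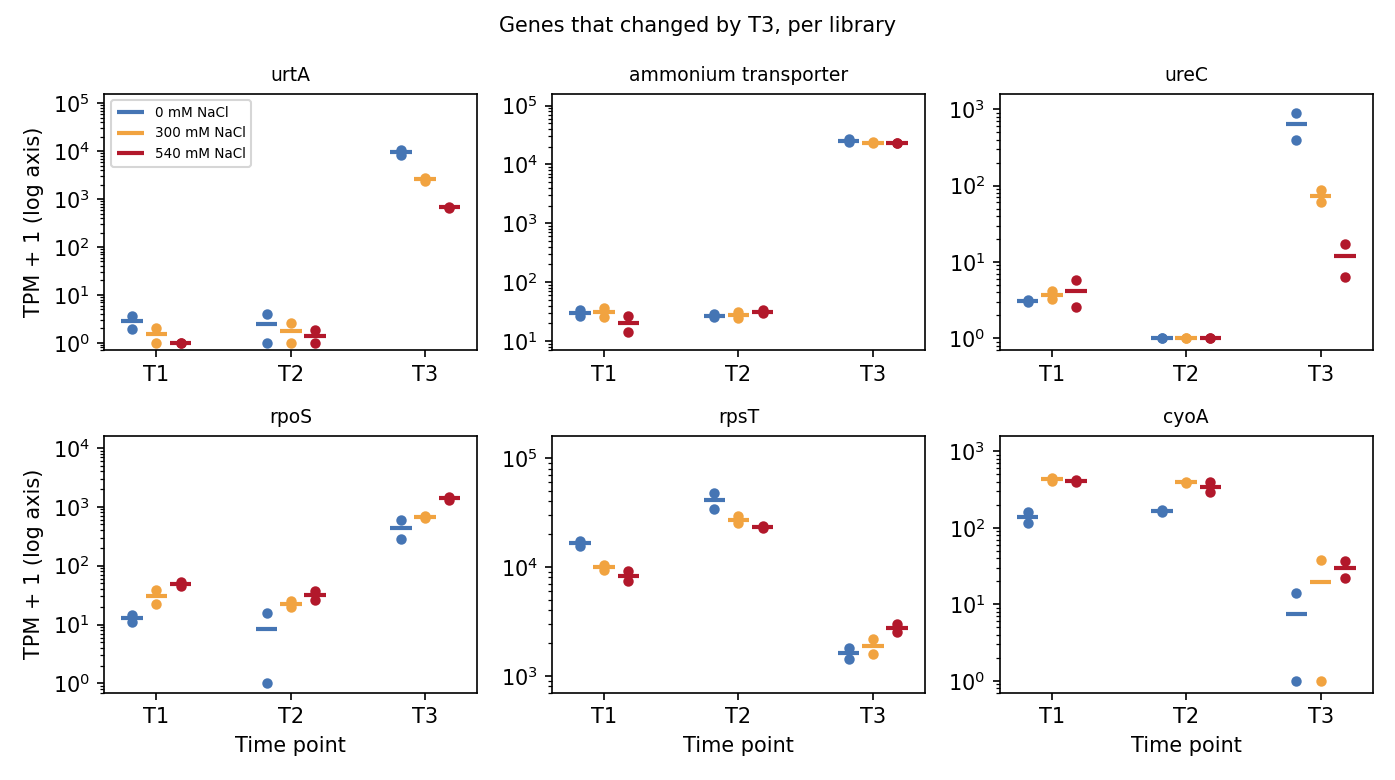
TPM + 1 on a log axis for 6 genes at the 3 time points, coloured by NaCl concentration, with points for the 2 libraries and bars for the group mean. The urea importer gene urtA and the ammonium transporter were near their T1 level at T2 and high at T3, urtA and ureC were lower at T3 the more NaCl the medium held, and rpsT and cyoA were low at T3.

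All 6 nitrogen assimilation genes deep enough to test rose (median log2 fold change 5.17; camera adjusted p = 0.00472, and adjusted p = 0.136 with an estimated correlation). Among them glnG, the response regulator of nitrogen control, rose from 42.0 to 1373 ± 247 TPM (5.01 ± 0.14, adjusted p = 2.44e-11), and its sensor glnL rose by 5.34 ± 0.18. In the same list the nitrite reductase subunits WP_014233998.1 and WP_020333805.1 rose by 10.72 ± 0.61 (adjusted p = 5.30e-09) and 9.47 ± 0.44 (adjusted p = 9.63e-10). At 540 mM WP_014233998.1 had 0 reads at T1, so its rise there was at least 58.9-fold above the floor of 3 reads per library. The stationary phase list had 8 of 9 genes risen and 1 fallen, against 5 and 1 under median-of-ratios scaling (camera adjusted p = 0.0414, and adjusted p = 0.323 with an estimated correlation). There the stationary phase sigma factor gene rpoS rose from 30.1 ± 17.4 to 835 ± 451 TPM (4.78 ± 0.52, adjusted p = 2.35e-06). Transcripts of rmf, whose product parks ribosomes as dimers, rose from 187 to 3655 ± 1674 TPM (4.18 ± 0.20, adjusted p = 1.27e-09). Of 13 flagellar genes 12 rose and 0 fell, against 9 and 1 under median-of-ratios scaling (camera adjusted p = 0.0203, and adjusted p = 0.323 with an estimated correlation).

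Of 56 ribosomal protein genes 55 fell and 1 rose (camera adjusted p = 2.64e-13, and adjusted p = 0.136 with an estimated correlation). Respiration and ATP synthase genes fell in 16 of 17 cases (camera adjusted p = 5.87e-05, and adjusted p = 0.323 with an estimated correlation), with atpA going from 4540 to 549 ± 162 TPM (-3.11 ± 0.17, adjusted p = 3.13e-09). Sulfur assimilation and methionine genes had 16 of 18 fallen and 2 risen (camera adjusted p = 0.00254, and adjusted p = 0.323 with an estimated correlation), with cysI at -3.98 ± 0.16 and metF at -4.81 ± 0.25. All 8 pentose phosphate genes fell (camera adjusted p = 0.0203, and adjusted p = 0.353 with an estimated correlation), among them the glucose-6-phosphate dehydrogenase gene WP_014231951.1 at -4.16 ± 0.62. Sodium transport had 7 of 9 fallen and 1 risen (camera adjusted p = 0.0215, and adjusted p = 0.323 with an estimated correlation). Here nqrF of the sodium-pumping NADH dehydrogenase fell by 3.34 (SE 0.15) and the antiporter WP_020333874.1 rose by 4.98 ± 0.35. Branched-chain amino acid synthesis had 10 of 11 fallen and 1 risen (camera adjusted p = 0.0243, and adjusted p = 0.360 with an estimated correlation). The counts for all 9 called lists were the same when adjusted over the list alone. The largest falls of single genes included metR (-5.95 ± 0.36, adjusted p = 8.04e-09), an activator of methionine synthesis, and pyrE (-5.29 ± 0.33, adjusted p = 1.01e-08) and pyrB (-5.11 ± 0.67, adjusted p = 1.20e-05) of pyrimidine synthesis.

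Of 1176 genes 1008 passed between T3 and T1, 505 higher and 503 lower, and 774 of them changed at least 2-fold. Under median-of-ratios scaling, with a shift of -0.56, 984 passed with 373 higher and 611 lower. With the T3 depth filter left out 2115 genes passed, 1336 higher and 779 lower, so the even split holds only for the 1176 deeper genes and without that scaling.

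From T2 to T3 the transporter protein WP_014234123.1 rose by 11.72 ± 0.43 (adjusted p = 1.77e-10) and the P-II regulator WP_005386570.1 by 10.62, while metR fell by 5.68 and pyrE fell by 5.09. Ribosomal protein genes had 55 of 56 fallen and 0 risen (camera adjusted p = 5.13e-15, and adjusted p = 0.0981 with an estimated correlation). Nitrogen genes had 6 of 6 risen (camera adjusted p = 0.00437, and adjusted p = 0.0981 with an estimated correlation). Respiration had 16 of 17 fallen (camera adjusted p = 7.53e-05) and flagellar genes 12 of 13 risen, or 10 risen and 1 fallen under median-of-ratios scaling (camera adjusted p = 0.00656), each with an adjusted p = 0.274 with an estimated correlation. Sulfur assimilation, with 15 of 18 fallen and 2 risen, had a camera adjusted p = 0.00437 and an adjusted p = 0.300 with an estimated correlation. All 8 pentose phosphate genes fell, sodium transport had 7 of 9 fallen and 1 risen, the stationary phase list 7 of 9 risen and 1 fallen, and histidine and tryptophan synthesis 11 of 13 risen, or 5 risen and 2 fallen under median-of-ratios scaling. Their tests gave, in this order, camera adjusted p = 0.0235, 0.0235, 0.0476 and 0.0373, and an adjusted p between 0.274 and 0.325 with an estimated correlation. The counts for these lists were the same when adjusted over the list alone. Of 1176 genes 992 passed, 510 higher and 482 lower, and under median-of-ratios scaling, with a shift of -0.63, 987 passed with 373 higher and 614 lower. With the T3 depth filter left out 2073 passed, 1341 higher and 732 lower.

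The last comparison tested whether the change with 540 mM NaCl differed between T3 and T1. The ectoine synthase WP_014235031.1 had 22.1 TPM without salt and 12.2 TPM with salt at T1, and 46.7 and 9598 TPM at T3. The log2 fold changes differed by 10.90 ± 2.45 (n = 2 libraries per group, adjusted p = 0.00908). The size of this difference depends on the pseudocount, since the T3 level without salt lay under the floor of 3 reads. The proline importer PutP, WP_020333510.1, had 5.15 and 3.25 TPM at T1, and 57.2 ± 24.7 and 5409 ± 359 TPM at T3 (difference 7.33 ± 1.18, adjusted p = 0.00202). In contrast, the rise of proX with salt was smaller at T3 than at T1 (difference -3.99 ± 0.88, adjusted p = 0.00817), as was that of the BCCT importer WP_020335534.1 (-2.93 ± 0.38, adjusted p = 4.66e-04). The T1 level of proX without salt lay under the floor of 3 reads, so the size of its difference is not exact. The urease gene ureC fell with salt at T3, where it had 641.7 TPM at 0 mM and 10.8 TPM at 540 mM (log2 fold change -5.82 ± 0.65, adjusted p = 6.51e-05; difference from T1 -6.15 ± 0.92, adjusted p = 0.00144). Transcripts of ureC were scarce at T1 with and without salt, and those of ureE had 0 reads at 0 mM T1. A fall with salt could thus hardly show at T1.

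Ribosomal protein genes differed as a set, with 20 of 56 higher in their salt response at T3 and 0 lower (23 when adjusted over the list alone, 14 under median-of-ratios scaling and 32 without 0 mM T3 B; camera adjusted p = 4.97e-04, and adjusted p = 0.544 with an estimated correlation). The envelope stress list did so with 6 of 11 higher and 0 lower (10 when adjusted over the list alone; camera adjusted p = 0.00338, and adjusted p = 0.0984 with an estimated correlation). There rpoE had a difference of 1.26 ± 0.25 and bamA, for the core of outer membrane protein assembly, 1.19 ± 0.24. Glycolysis differed the other way with 4 of 8 lower and 0 higher (4 when adjusted over the list alone; camera adjusted p = 0.0201, and adjusted p = 0.544 with an estimated correlation). Examples are tpiA at -1.60 ± 0.28 and pfkA at -1.38 ± 0.27. Differences of type B L31, WP_020335158.1 (8.25 ± 2.12), and the importer subunits WP_020334791.1 (10.56 ± 2.27) and WP_020334792.1 (7.49 ± 1.96) came to 5.15, 7.01 and 4.83 without 0 mM T3 B, in which these genes were far under replicate A. The calls of WP_020335158.1 and WP_020334792.1 were lost without 540 mM T1 A or 0 mM T1 B, and also without 540 mM T3 B for the former and 540 mM T3 A for the latter, at adjusted p of up to 0.0711.

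The difference passed for 258 of 1176 genes, 169 higher and 89 lower, and under median-of-ratios scaling, with a shift of -0.27, for 229 with 103 higher and 126 lower. With libraries thinned to the shallowest 56 genes passed and 12 of the 17 gene results followed lost their call, with array weights by time point 132 and 3. Without 0 mM T1 A 144 genes passed, without 0 mM T1 B 154, without 540 mM T1 A 164 and without 540 mM T1 B 147. The call of the SDR family oxidoreductase WP_020336062.1 (-5.77 ± 1.90) was lost in 15 of 18 and that of WP_014231295.1 (-8.74 ± 2.70) in 13 of 18 such fits, at adjusted p of up to 0.147. For 300 mM against 0 mM the same test passed for 133 genes, 82 higher and 51 lower.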

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

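The tests of the second ectoine synthase and of library 0 mM T3 B below were chosen after the results were seen.

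The change with salt differed between T3 and T1 by a direct test for 258 of 1176 genes at 540 mM and for 133 at 300 mM NaCl. Without 0 mM T1 A, 0 mM T1 B, 540 mM T1 A or 540 mM T1 B the 540 mM count was 144, 154, 164 or 147. As sets, ribosomal protein genes (adjusted p = 4.97e-04, 20 of 56 higher), envelope stress genes (adjusted p = 0.00338, 6 of 11 higher) and glycolysis genes (adjusted p = 0.0201, 4 of 8 lower) differed with the preset correlation, and at adjusted p = 0.544, 0.0984 and 0.544 with an estimated correlation. Differences of the log2 fold change with 540 mM NaCl, T3 less T1, were 10.90 for the ectoine synthase WP_014235031.1, 7.33 for the proline importer WP_020333510.1, 1.26 for rpoE and 1.19 for bamA. They were -3.99 for proX, -2.93 for the BCCT importer WP_020335534.1, -0.83 for the porin WP_020333911.1, -6.15 for ureC, -1.38 for pfkA and -1.60 for tpiA. The glutamine synthetase WP_020332829.1 differed by -7.54, the histidinol-phosphate transaminase WP_024373008.1 by -5.47, the oxidoreductase WP_020336062.1 by -5.77 and WP_014231295.1 of the YfbU family by -8.74. Transcripts of ureC and WP_020332829.1 were scarce at T1 also without salt, where a fall could hardly show. Type B L31, WP_020335158.1, differed by 8.25 and the importer genes WP_020334791.1 and WP_020334792.1 by 10.56 and 7.49. Each of these 17 differences had an adjusted p under 0.05, and none changed its sign without any 1 library. The calls of WP_014231295.1, WP_020332829.1, WP_020333911.1, WP_020334792.1, WP_020335158.1 and WP_020336062.1 were lost without at least 1 library, at adjusted p of up to 0.147, while the other 11 kept theirs. With libraries thinned to the shallowest 12 of the 17 calls were lost, with array weights by time point or a pseudocount of 0.1 3 each, and with each of the 3 other filters or the T3 depth filter left out 2.

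The ectoine synthase WP_014235031.1 was high with salt at T3 and not at T1. The sizes of its log2 fold changes rest on a T3 level without salt under the floor of 3 reads. Unequal depth of the T3 libraries is argued against, since with every library thinned to the shallowest the log2 fold change at T3 was 9.87 (adjusted p = 0.00608). Reads shared with the other ectoine synthase, WP_020336355.1, are argued against too, since the ratio of their TPM was at most 0.00514 in T1 and T2 libraries with salt and at least 3.41 in those of T3. The scaling of TPM is argued against by a difference of 10.55 under median-of-ratios scaling (adjusted p = 0.0122). A biological difference in how the cultures respond to salt at T3 stays open as a hypothesis, found and tested on the same data.

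In library 0 mM T3 B 24 genes were far under all other T3 libraries, and 8 were far above them, among them ureG with 1670 TPM against at most 282. Type B L31 had 181 TPM against at least 12060, ykgO 0 TPM against 8010, znuA 13.1 TPM against 369 and zrgA 17.1 TPM against 268. Too few reads as the whole cause are argued against, since the same rule found 11, 4 and 1 low genes in the 3 T3 libraries with fewer reads in all. A wrong label within the series is argued against by its correlation of 0.793 with replicate A, against at most 0.713 with a library of another group, and reads given to rpmE and rpmJ by their gain, 3.86% of the TPM that the type B genes lack. No biological explanation was tested, since the design gives none for a single library.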

How the results depend on the processing

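The array weights, means of log2 values, summed reads, left-out cultures, omission of the T3 depth filter (also with thinning, for the nitrogen list) and, for single time points and time, thinning were chosen after the data had been seen. DESeq2 was not run, because TPM was kept as the unit, although the recovered reads would have allowed a count-based test. No ribosomal RNA genes were listed to keep, and voom was not run for salinity at single time points. Where a left-out library leaves 1 in its group, that library is assumed to vary like the other groups. Unless a reason is given, the cause of a change below was not tested. Gene results were followed for the genes named in the text and others that meet the rule for named genes, 226 in all and 223 of them called. Of these 223, 165 kept their call in every fit with 1 library or culture left out and 58 lost it in at least 1. Over the alternatives, 5445 values kept direction and call, 377 lost the call, 9 gained it and 23 reversed. Depth limits the genes that can be tested, 1176 with T3 against 3078 without. Thinning to the shallowest library kept the calls of all 22 results followed at T3, 37 for T3 against T1 and 10 for T3 against T2, and ended 14 of 54 for 540 against 0 mM, 8 of 21 for 300 against 0 mM, 4 of 5 for 540 against 300 mM, 5 of 19 for T2 against T1, 12 of 22 at T1, 5 of 19 at T2 and 12 of 17 for the difference of the changes. The letters were not taken to pair the samples, since not every correlation by letter was over 0.1. That rule does not exclude an effect shared by libraries of one letter. In most groups library B had more reads than A, as with 547430 against 205286 at 0 mM T1. At 300 mM T3 it had fewer, 44273 against 49351. The fits with the letter or culture as a block, given below, called more genes in each comparison. After group means were removed, the correlation between libraries sharing a letter ran from -0.0487 to 0.377 over the 36 pairs of groups, with a median of 0.130 and 24 over 0.1. For the 9 pairs of time points within a culture label the median was 0.116, with 6 over 0.1.

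With libraries thinned to the shallowest, fewer reads gave fewer genes: 166 for 540 against 0 mM, 70 for 300 against 0 mM, 1 for 540 against 300 mM, 47 at T1, 50 at T2, 188 at T3, 60 for T2 against T1 and 56 for the difference of the changes. Leaving out T2 gave 348 genes for 540 against 0 mM and 196 for 300 against 0 mM. The mean of log2 values gave 290 and 141, and the unsummed libraries gave 496 for 300 against 0 mM. The block by letter gave 503 for 300 against 0 mM, and 748, 6, 152, 190, 585, 149, 1008, 1010 and 286 for 540 against 0 mM, 540 against 300 mM, T1, T2, T3, T2 against T1, T3 against T2, T3 against T1 and the difference, the last 4 with the culture as block. The block also gave mscS a call for 540 against 0 mM (adjusted p = 0.0188) and changed no other call of the gene results followed.

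For 540 against 300 mM, the unsummed libraries and voom each gave 29 genes, 25 and 20 of them higher. Leaving out T3, the mean of log2 values and the summed reads each gave 0 in limma, with 250, 188 and 406 genes at an unadjusted p under 0.05. Array weights gave 369 genes at T1, 488 at T2, 178 at T3, 408 for T2 against T1 and 132 for the difference. More genes were tested at T3 with no filter, with at least 1 TPM in every library of a group, with at least 1 TPM in 2 libraries, or with the T3 depth filter left out, which gave 926, 965, 936 and 871 genes at T3, 2189, 2222, 2197 and 2073 for T3 against T2, and 2245, 2273, 2258 and 2115 for T3 against T1. Only the 4 libraries compared gave 62 at T3. For T2 against T1, voom gave 501 and a change of at least 2-fold 35.

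With each culture left out in turn the counts ran from 97 to 415 for 540 against 0 mM (99 without 540 mM A, 97 without 540 mM B), from 45 to 266 for 300 against 0 mM (45 and 95 without 300 mM A and B, 108 and 113 without 540 mM A and B) and from 0 to 12 for 540 against 300 mM (12 without either 0 mM culture, 0 without any of the others). With each library left out they ran from 45 to 200 at T1 (47 without 0 mM T1 A, 45 without 540 mM T1 A, 199 and 200 without 0 mM T3 A and B), from 58 to 273 at T2 (58 and 66 without 540 mM T2 A and B, 273 without either 0 mM T3 library), from 358 to 580 at T3, from 967 to 1015 for T3 against T2 and from 981 to 1024 for T3 against T1. For T2 against T1 they ran from 70 to 245 (70 without 0 mM T1 A, 78 without 300 mM T1 A, 73 without 300 mM T2 A or 540 mM T1 A, 76 without 540 mM T2 A, 74 without 300 mM T2 B, 75 without 540 mM T2 B, 245 without either 0 mM T3 library) and for the difference from 144 to 349 (144 and 154 without 0 mM T1 A and B, 164 and 147 without 540 mM T1 A and B).

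With the estimated correlation the called lists went from 4 to 0 for 540 against 0 mM, 5 to 0 for 300 against 0 mM, 1 to 0 for 540 against 300 mM, 8 to 1 at T1, 8 to 2 at T2, 6 to 0 at T3, 11 to 2 for T2 against T1, 9 to 0 for T3 against T2 and for T3 against T1, and 3 to 0 for the difference. With the block the fermentation list lost its call for 300 against 0 mM (adjusted p = 0.058), which left 4, while 540 against 300 mM gained 4 lists for 5 in all and T2 gained 2 for 10, and the called lists of the other comparisons were the same.

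Leaving out T3 turned ureC to a log2 fold change of 0.28, uspA to 0.12, WP_020335943.1 to 0.45 and feoB to 1.57 for 540 against 0 mM, and the ectoine synthase WP_014235031.1 to -0.43 for 540 and -1.21 for 300 against 0 mM. For 540 against 0 mM feoB also turned to 0.44 unsummed and with the mean of log2 values, 0.17 with voom and 0.11 with summed reads. For 540 against 300 mM, WP_020335355.1 turned to 0.42 unsummed and with the mean of log2 values, 0.76 with voom and 1.37 without T3, and WP_020335356.1 to 0.067 unsummed and with the mean of log2 values, 0.18 with voom and 0.75 without T3. Likewise WP_024373008.1 turned to 0.030 unsummed and with the mean of log2 values, 0.17 with voom and 1.23 without T3, and WP_014233674.1 to 0.12 without T3.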

Other observations

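The tests of nitrogen and zinc supply, of lower depth and of background below were chosen after the results were seen, and those of other splits before.

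Beyond the groups above, 540 against 0 mM NaCl split the stress lists. Of 15 general stress and stationary phase genes 3 rose and 4 fell, against 2 and 5 under median-of-ratios scaling and 3 and 0 with T3 left out (4 and 5 when adjusted over the list alone; camera adjusted p = 0.298). The stationary phase sigma factor gene rpoS rose by a log2 fold change of 1.74 ± 0.31 (adjusted p = 0.0161, n = 2 cultures each) and uspB by 1.64 ± 0.26 (adjusted p = 0.0116), while uspA fell by 1.59 (SE 0.20, adjusted p = 0.00488) and the ribosome-binding factor RaiA, WP_020335943.1, by 1.91 (SE 0.25, adjusted p = 0.00551). Of 25 oxidative stress genes 6 rose and 0 fell, against 1 risen under median-of-ratios scaling (6 when adjusted over the list alone; camera adjusted p = 0.167), among them the thiol peroxidase gene bcp at 1.15 ± 0.19 (adjusted p = 0.0137). Of 14 cold shock genes 3 fell and 1 rose, against 5 and 0 under median-of-ratios scaling (4 and 3 when adjusted over the list alone; camera adjusted p = 0.0949), with the cold shock proteins WP_014233736.1 at -1.61 ± 0.21 and WP_014234032.1 at -1.14 ± 0.14. With T3 left out uspA stood at 0.12 and WP_020335943.1 at 0.45. Without 540 mM A the calls of rpoS, bcp, uspA, WP_020335943.1 and WP_014233736.1 were lost, and without 540 mM B those of rpoS, bcp, uspB and WP_014234032.1, at adjusted p of up to 0.113.

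Iron genes went both ways at 540 against 0 mM, with 3 of 28 risen and 2 fallen, against 1 and 5 under median-of-ratios scaling (4 and 3 when adjusted over the list alone; camera adjusted p = 0.958). The siderophore receptor WP_049873777.1 rose by 2.38 ± 0.33 (adjusted p = 0.00711, n = 2 cultures each) and stood at 1.86 without 0 mM B (adjusted p = 0.00416), whose T3 library had 21.65 TPM of it, from 4 reads, against at least 144.3 TPM in the other T3 libraries. In turn feoB, the permease for ferrous iron, fell by 1.41 (SE 0.30, adjusted p = 0.0263). Of 22 sulfur and methionine genes 4 rose and 0 fell, against 4 and 2 under median-of-ratios scaling (4 when adjusted over the list alone; camera adjusted p = 0.158), with the sulfate importer gene cysZ at 2.06 ± 0.29 (adjusted p = 0.00711). With T3 left out WP_049873777.1 stood at 2.09 and feoB at 1.57 (adjusted p = 0.0252). Without 540 mM A or 540 mM B the calls of feoB, cysZ and WP_049873777.1 were lost, and that of feoB without 0 mM A as well, at adjusted p of up to 0.152.

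The nitrogen list was higher at T3 than at T1 (camera adjusted p = 0.00472, and adjusted p = 0.136 with an estimated correlation). Of its 29 members 16 passed the filter on low values. With libraries thinned to the shallowest and the T3 depth filter left out, 14 of these 16 kept their call. The median log2 fold change of the 16 was then 5.06. This argues against lower depth of the T3 libraries for the 14 that kept their call. Depth stays open for napA, at 0.97 (adjusted p = 0.447), and WP_014234175.1, at 1.40 (adjusted p = 0.123). The 1355 genes under 5 TPM at T1 and T2 had a median of 5.85 TPM at T3. This is 2.34% of the median of 249.5 TPM of the 16 members, which were kept by a filter on low values. It argues against an even background such as genomic DNA for members at or above that median only. For weaker members background stays open, since a median does not show their levels. Nitrogen running low by T3 is a candidate explanation that these files leave open, because the list measured is the one whose rise prompted it and the medium was not measured. Over all members that pass the filter on low values, the median log2 fold change was 4.73 for nitrogen (16 of 16 risen), 1.06 for phosphate (8 of 13 risen, 3 fallen), 0.54 for iron (9 of 28 risen, 6 fallen) and -1.85 for sulfur (4 of 22 risen, 17 fallen), and these medians were not tested against one another. A member nearly silent at T1 and T2 passes that filter only through its T3 level, which favours rises. The filter also left out unequal shares, since the phosphate, iron and sulfur lists held 24, 32 and 22 members in all.

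The type B ribosomal proteins L31 and L36 were higher at T2 than at T1, and in many bacteria such paralogs replace zinc-binding forms when zinc is scarce. Zinc running low by T2 is a candidate explanation that stays open, since the 4 genes below were chosen after their values were seen and zinc was not measured in these files. Of the 4 genes znuA, znuB, znuC and zrgA, 3 rose at T2: znuA by 2.99 ± 0.57 (adjusted p = 0.0122, n = 6 libraries each), znuC by 2.23 ± 0.23 (adjusted p = 1.96e-04) and zrgA by 3.15 ± 0.50 (adjusted p = 0.00363), while znuB stood at 1.86 ± 0.64 (adjusted p = 0.143, and 0.00613 and 0.00549 without 0 mM T3 A and B).

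For the time comparisons, libraries were split at random within each salinity, 100 splits each with the real one included. For T2 against T1 only 1 of the 100, the real split, gave as many genes, 147 against at most 8 in the others. For T3 against T2 it was 1 of 100, with 992 genes against at most 753, and for T3 against T1 1 of 100, with 1008 against at most 769. The real split thus gave the most genes in all 3, at the smallest share that 100 splits can show. This makes chance unlikely but does not exclude it. Some splits keep the real time contrast in part, since they were drawn separately within each salinity, and the culture label was not kept.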
